A study of Mus musculus with 9 samples.

How the data were processed

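Ventral hippocampus tissue of 9 male C57BL/6J mice, 8 weeks old when housed, was sequenced as total RNA, with 3 mice in each of 3 groups. The labels name sedentary controls (SED), stress-susceptible mice (SUS) and stress-susceptible mice with low-intensity exercise (SUS_LE). Restraint lasted 2 hours a day for 14 days, and exercise 2 weeks, per the labels. The labels do not state how susceptibility was scored or how long after the last session tissue was taken. Each library comes from a named mouse, so p values here measure the spread between separate animals. All libraries carry the same batch number. RNA was extracted with RNAiso Plus, and libraries were made with the CORALL RNA-seq V2 kit, per the labels.

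The deposited files hold counts per gene symbol, 1 file per library with 40213 genes each, as whole numbers that were not normalized. Per the submitters' processing notes, the authors used fastp, STAR and Salmon on GRCm39, with no versions given. The annotation, the strand setting, the use of molecular identifiers and whether the counts were rounded from Salmon estimates are not stated. Column headers number the exercised libraries 2 to 4, and the labels 1 to 3; the labels' numbers are used here. Every column of the files was used. Library totals ran from 14172344 to 15582304 counts. A gene with 0 counts in 1 library of this size has an upper 95% limit of 3 counts. No duplicated library was found: between libraries of the same group the chi-square per degree of freedom of the counts was 2.82 to 15.8.

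Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by the edgeR filter on expression with group sizes given, which left 16106 genes holding 99.9% of counts, and libraries were scaled by TMM factors. A quasi-likelihood model of edgeR with robust dispersion was fitted to all 9 libraries, with group as the only term, and gave a common biological coefficient of variation of 0.0845. The 3 comparisons were SUS against SED, SUS_LE against SUS and SUS_LE against SED, with an F test for any difference among the groups. P values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. For edgeR and limma the adjustment was over all tested genes. DESeq2 was run with its independent filtering, so that 11241, 10617 and 6 of the 16106 genes had no DESeq2 adjusted p in the 3 comparisons. Named genes were the 5 with the smallest p in each direction whose mean log2 CPM was above 0, the 4 members with the smallest p of lists past the threshold, and 10 genes of cilia, astrocytes, stress and activity that were always given. Log2 CPM used a prior count of 2.

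Groups, comparisons, 35 gene lists and alternatives were fixed before the data were examined. The lists, from general knowledge and not from these samples, cover primary and motile cilia, cell types and regions of the hippocampus and its neighbours, and pathways of stress, activity, immunity and metabolism. Of 920 members 918 were found in the files, and 23 genes stand in more than 1 list. The erythrocyte list includes genes that neurons also express. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, adjusted over the 35 lists of a comparison, and again with an estimated correlation and by fry. Members were also adjusted over their list alone. Counts of members past the threshold over the list alone or over all genes are from edgeR. DESeq2 called members of several lists, and some of those counts are given. List scores per library are the mean log2 CPM of the members, centred on the 9 libraries. With 3 against 3 libraries an exact permutation test cannot give a p under 0.1.

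SUS against SED and SUS_LE against SUS share the SUS libraries. The covariance of their fold changes was therefore set against simulated counts with no group difference and the same dispersions. Changed genes and lists were also counted in every split of the 6 libraries of a comparison into groups of 3, 10 for each, and in 100 splits drawn at random, the real one included, for the test among the 3 groups. GC content and transcript length came from GENCODE M21, a GRCm38 annotation, matched by symbol for 91.5% of tested genes, and were used for trends only. Alternatives fixed beforehand were DESeq2, limma voom with quality weights, other scaling factors, no filter or a stricter one, only 2 groups in the fit, replicate number as a block, dispersion without the robust step, leaving out each library, and camera with an estimated correlation. Alternatives chosen after seeing the data were a choroid plexus score as a covariate, leaving out the 3 libraries lowest in Ttr, per-library GC and length trends removed by offsets (in edgeR and in DESeq2), TMM factors in DESeq2, DESeq2 without independent filtering, DESeq2 without each library, and fold change covariance among genes apart from the choroid plexus score (absolute r under 0.7, with score and genes centred within groups or not) or with GC trends removed. The closing section gives the effect of these alternatives. Leaving out the 3 libraries lowest in Ttr keeps only SUS_LE 2 among the exercised mice. P values of SUS_LE comparisons in that setting hold no spread between exercised mice. The choroid plexus score did not overlap between SED and SUS_LE, so as a covariate it cannot be cleanly parted from that comparison.

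The pipeline was tested on simulated data of the same depth and spread, with 50 genes changed at each fold. Changed genes had a mean log2 CPM of at least 0. Simulated genes varied independently, without trends of GC, length or choroid plexus content, so the rates may not hold for the real libraries. At 1.5-fold edgeR recovered 58.0%, 70.0% and 66.0% of them in the 3 comparisons, and at 2-fold 84.0%, 76.0% and 84.0%, with 8, 3 and 12 unchanged genes called. A simulated covariance of −0.0223 was recovered as −0.0231.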

Results

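Ventral hippocampus from 9 male mice was compared in 3 groups of 3: sedentary controls (SED), mice susceptible to 14 days of restraint (SUS), and susceptible mice given 2 weeks of low-intensity treadmill exercise (SUS_LE). Levels are in CPM, counts scaled to library size, given as mean ± SD of 3 mice. Fold changes are log2 values with the standard error (SE). Choroid plexus transcripts differed more between libraries than any other of the 35 gene lists (mean log2 score −2.91 to 2.06). Ttr, the thyroid hormone carrier made by choroid plexus epithelium, stood at 4310, 3543 and 2935 CPM in SED 1 to 3, at 27.4, 2659 and 6085 in SUS 1 to 3, and at 83.2, 1509 and 59.6 in SUS_LE 1 to 3. SUS 1, SUS_LE 1 and SUS_LE 3, the 3 libraries lowest in Ttr, stood apart on the first principal component (31.5, 22.8 and 24.6, against −25.4 to 2.7 in the others), which held 30.0% of the variance. Meningeal fibroblast genes were lowest in SUS 2 (mean log2 score −1.02, against −0.21 to 0.43 in the others), and interferon response genes were highest in SUS_LE 3 (0.59, against −0.22 to 0.07).

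**Figure D1:**
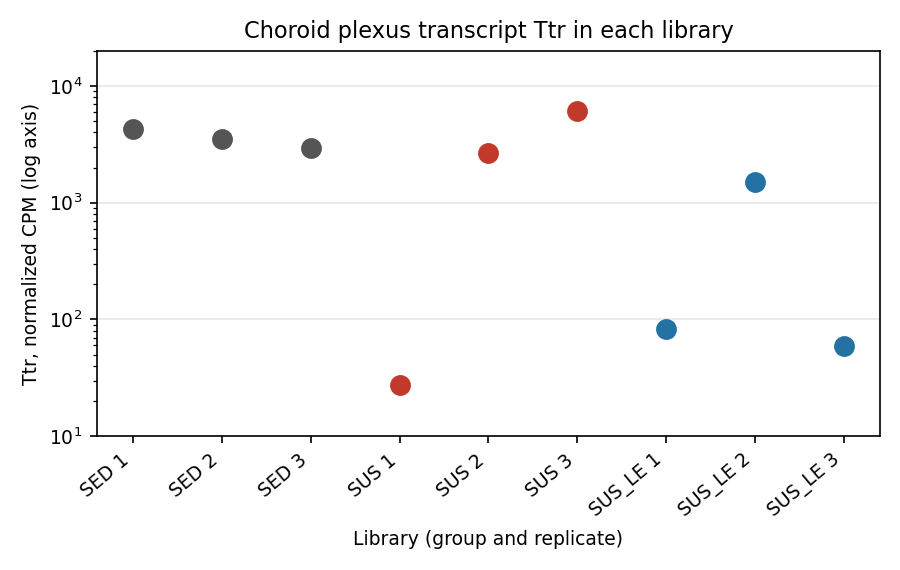
Ttr level in each of the 9 libraries on a log axis, by group. Each point is 1 mouse.

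Between SUS and SED, Doc2a, a calcium sensor of transmitter release, stood at 11.7 ± 0.318 CPM in SUS and 7.16 ± 0.481 in SED (log2 fold change 0.71, SE 0.12, edgeR adjusted p = 0.0738). Nr4a1, an activity-induced nuclear receptor (0.46, SE 0.09), Tuba4a, an alpha-tubulin (0.26, SE 0.05), Gng3, a neuronal G protein subunit (0.30, SE 0.06), and Rexo4 (0.38, SE 0.07) were next (edgeR adjusted p = 0.0929 for each). Among genes with lower values, Acap2, a GTPase-activating protein of endosomal traffic, stood at 139 ± 3.74 CPM in SUS and 173 ± 8.99 in SED (−0.32, SE 0.05). Beside it were the kinase Taok1 (−0.35, SE 0.06), the cadherin Fat4 (−0.43, SE 0.08) and Gm32584 (−0.94, SE 0.17, edgeR adjusted p = 0.0738 for all 4), and then Nkain3 (−0.38, SE 0.07, edgeR adjusted p = 0.0929). In each of these genes, picked for small p, the 3 SUS values did not overlap the 3 SED values, as in 18.3% of all tested genes. By edgeR 0 of 16106 genes passed an adjusted p of 0.05, with 2108 under an unadjusted p of 0.05 where 805 were expected by chance. Fold changes followed GC content (rho 0.352) and transcript length (−0.233), and with those trends removed 1404 genes were under an unadjusted p of 0.05 and the smallest edgeR adjusted p was 0.226. Limma voom called 0 and DESeq2 163 (80 higher, 83 lower, adjusted p = 0.000192 for Acap2 and 0.000359 for Taok1). Its independent filtering left 11241 genes without an adjusted p, Doc2a and Nr4a1 among them, and without that filtering it called 53. The edgeR count was 3 without SED 2, 27 without SUS 2, 74 without SUS 3 and 14 without the 3 libraries lowest in Ttr. The DESeq2 count was 8, 100 and 7 without SED 1, 2 and 3, 25, 277 and 273 without SUS 1, 2 and 3, 72 and 70 without SUS_LE 1 and 2, and 20 with GC and length trends removed.

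Genes of protein synthesis and oxidative phosphorylation were higher in SUS than in SED by small steps. Of 78 cytosolic ribosomal protein genes 71 had higher values (mean log2 fold change 0.10, camera adjusted p = 2.09e-11, adjusted p = 0.697 with an estimated correlation). When adjusted over the list alone 12 passed, against 0 over all genes, among them Rpl32 (0.21, SE 0.06), Rps15 (0.19, SE 0.05), Rpl26 (0.17, SE 0.05) and Rpl35 (0.20, SE 0.06). Nuclear encoded genes of oxidative phosphorylation had higher values in 62 of 74 members (mean 0.08, camera adjusted p = 5.25e-07, adjusted p = 0.697 with an estimated correlation, 0 members over the list alone or over all genes). They include the ATP synthase subunits Atp5e (0.31, SE 0.09) and Atp5g3 (0.17, SE 0.05). Immediate early genes, which neuronal activity induces, had higher values in 19 of 27 members (mean 0.14, camera adjusted p = 0.0361, adjusted p = 0.697 with an estimated correlation). Npas4 (0.70, SE 0.19), Nr4a1 and Arc (0.34, SE 0.09) passed over the list alone, and 0 over all genes. Fos, of the same list, stood at 5.60 ± 1.28 CPM in SUS and 6.84 ± 1.70 in SED (−0.29, SE 0.20, edgeR adjusted p = 0.569). The immediate early list no longer passed without SED 1 (mean 0.11, camera adjusted p = 0.165), SED 2 (0.16, 0.0577), SUS 2 (0.13, 0.142) or SUS 3 (0.14, 0.0669), or with GC and length trends removed (0.13, 0.0675).

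Myelin genes were lower in SUS than in SED: all 24 members had lower values (mean −0.18, camera adjusted p = 3.82e-06, adjusted p = 0.697 with an estimated correlation). By edgeR 6 passed over the list alone and 0 over all genes, among them Tspan2 (71.0 ± 7.89 against 91.9 ± 2.05 CPM, −0.37, SE 0.07), Ermn (−0.29, SE 0.07), Ugt8a, the galactolipid synthase of myelin (−0.30, SE 0.07), and Mal (−0.27, SE 0.07). DESeq2 called 4 myelin genes lower. Mitochondrially encoded genes had lower values in 11 of 13 members (mean −0.07, camera adjusted p = 0.0245, adjusted p = 0.697 with an estimated correlation). Of these ATP8 (−0.23, SE 0.07) passed over the list alone and 0 over all genes. Reactive astrocyte genes (23 of 28 lower, mean −0.18, camera adjusted p = 0.0167) and vascular genes (17 of 20 lower, mean −0.15, camera adjusted p = 0.0392) also stood lower, each with 0 members over the list alone and with adjusted p = 0.697 with an estimated correlation. The mitochondrial list no longer passed without SED 1 (mean −0.06, camera adjusted p = 0.0830) or SUS 3 (−0.04, 0.251). Nor did the reactive astrocyte list without SED 1 (mean −0.14, camera adjusted p = 0.0830), SUS 1 (−0.13, 0.0527) or SUS 2 (−0.09, 0.352), or with a choroid plexus score in the model (−0.14, 0.0503). Without SED 1, SUS 1 or SUS 2 the filter also admits Lcn2, a gene with few counts that the reactive astrocyte list holds. Those 3 means are therefore not over the same members as the main fit. The vascular list did not pass without SED 1 (mean −0.16, camera adjusted p = 0.0873), SED 3 (−0.13, 0.0921) or SUS 2 (−0.03, 0.618), and its mean was −0.24 without SUS 3 (0.00485). SUS 2, the library lowest in meningeal genes, was also lowest in the vascular (−0.37) and reactive astrocyte (−0.30) scores.

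Choroid plexus genes were lower in all 20 members in SUS (mean −1.45, camera adjusted p = 0.00331, adjusted p = 0.726 with an estimated correlation). Genes of motile cilia and ependymal cells were lower in 33 of 41 (mean −0.31, camera adjusted p = 0.0162, adjusted p = 0.726 with an estimated correlation). Each list had 0 members past the threshold over the list alone and over all genes. Both differences rested on SUS 1: without it the choroid plexus mean was 0.02 (camera adjusted p = 0.963) and the motile cilia mean 0.07 (0.540). Without SUS 3 they were −2.47 (camera adjusted p = 6.18e-07) and −0.54 (1.44e-05). The motile cilia list also did not pass without SED 1 (mean −0.21, camera adjusted p = 0.194).

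Some lists passed between SUS and SED only in other settings. In the main fit their adjusted p with an estimated correlation was 0.726 (meningeal and dentate) or 0.697 (cortex and striatum). The meningeal difference rested on SUS 2, which scored −1.02. SUS 1 and 3 scored 0.003 and 0.36, against 0.01 to 0.14 in SED. Dentate scores overlapped between SED (−0.16 to 0.13) and SUS (−0.16 to 0.01). So did cortex and amygdala scores (−0.13 to 0.07 and −0.11 to 0.22). Meningeal fibroblast genes (mean −0.29, camera adjusted p = 0.0817) passed without SUS 1 (−0.40, 0.0189) or SUS 3 (−0.58, 0.000190), with the replicate block (−0.29, 0.0181), with a choroid plexus score in the model (−0.38, 0.0279), without the 3 libraries lowest in Ttr (−0.40, 0.0250) and with GC and length trends removed (−0.30, 0.0113). Dentate granule cell genes (mean −0.09, camera adjusted p = 0.0803) passed without SED 2 (−0.18, 0.000955) or SUS 1 (−0.12, 0.0189), with the choroid plexus score (−0.10, 0.0395) and without the 3 libraries (−0.13, 0.0203). Cortex and amygdala genes (mean 0.13, camera adjusted p = 0.137) passed without SED 2 (0.19, 0.0486) or SUS 1 (0.22, 0.0239) and without the 3 libraries (0.22, 0.00821). Striatum genes (mean 0.23, camera adjusted p = 0.114) passed without SED 2 (0.35, 0.0486) and without the 3 libraries (0.33, 0.0252).

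No primary cilium list passed the test between SUS and SED. Intraflagellar transport and BBSome genes, which carry cargo along the cilium, had a mean of −0.02 (16 of 44 higher, camera adjusted p = 0.600). The mean was −0.04 for transition zone and basal body genes (13 of 40 higher, camera adjusted p = 0.143) and −0.00484 for ciliary membrane and Hedgehog signalling genes (14 of 37 higher, 0.623). Arl13b, the ciliary GTPase, stood at 7.23 ± 1.02 CPM in SUS and 8.81 ± 1.27 in SED (−0.28, SE 0.15, edgeR adjusted p = 0.418). Adcy3 stood at 46.5 ± 3.26 and 45.8 ± 1.52 (0.02, SE 0.07, 0.928), and Ift88 at 19.8 ± 1.12 and 18.5 ± 1.17 (0.10, SE 0.09, 0.664). Astrocyte genes did not shift in 1 direction (mean −0.02, median 0.01, camera adjusted p = 0.853). The mixed fry test, which counts change of either sign without comparing it with other genes, gave adjusted p = 0.0107. It gave the same adjusted p for the ribosomal and nuclear encoded oxidative phosphorylation lists, so it is not particular to astrocytes. Over the list alone 4 astrocyte genes passed, and 0 over all genes. These were the water channel Aqp4 (−0.22, SE 0.06) and the bicarbonate carrier Slc4a4 (−0.23, SE 0.05), with lower values, and Agt (0.29, SE 0.09) and S100b (0.23, SE 0.07), with higher values. DESeq2 called 3 astrocyte genes lower and 0 higher. Gfap, the astrocyte filament (0.08, SE 0.07, edgeR adjusted p = 0.668), Bdnf (0.09, SE 0.09, 0.702), the glucocorticoid receptor Nr3c1 (−0.14, SE 0.06, 0.348) and its target Fkbp5 (0.00, SE 0.14, 0.999) did not pass. Glucocorticoid responsive genes as a list did not either (mean 0.01, camera adjusted p = 0.492).

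**Figure D2:**
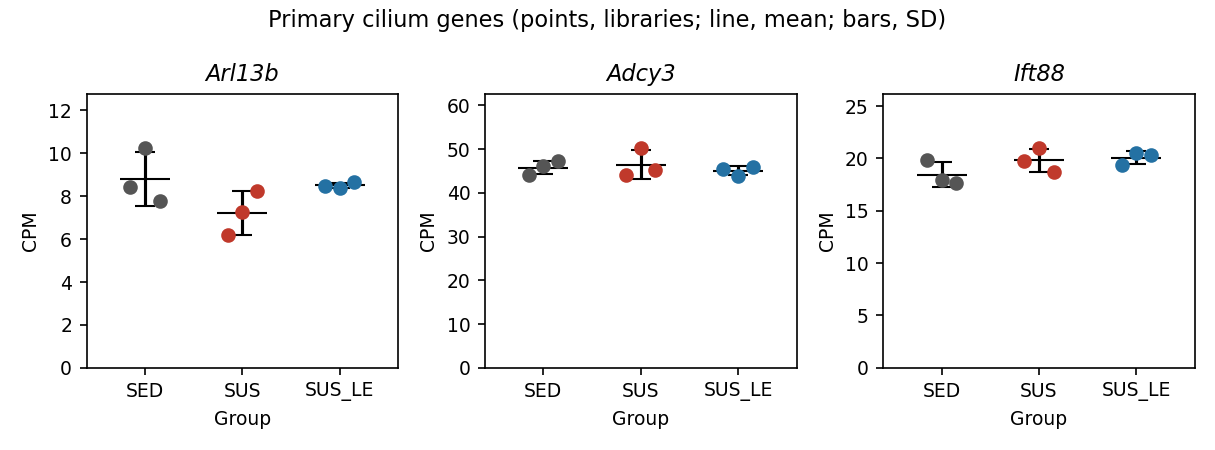
Levels of the primary cilium genes Arl13b, Adcy3 and Ift88 by group. Points are mice, lines the mean and bars the SD.

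Between SUS_LE and SUS, Acap2 had the smallest p, at 175 ± 3.8 CPM in SUS_LE and 139 ± 3.74 in SUS (log2 fold change 0.34, SE 0.05, edgeR adjusted p = 0.0560). Higher values in SUS_LE were also held by Dock10 (0.33, SE 0.06), the lysosomal traffic gene Lyst (0.37, SE 0.07) and Ints6l (0.37, SE 0.07, edgeR adjusted p = 0.0728 for each). The myelin gene Mal followed (0.37, SE 0.07, edgeR adjusted p = 0.0922). Lower values were held by Crocc, which codes for the rootlet of the cilium (60.0 ± 4.24 against 77.9 ± 5.40 CPM, −0.38, SE 0.07, edgeR adjusted p = 0.0735), and Myh14, a non-muscle myosin (−0.47, SE 0.08, 0.0728). Next were Zfp579 (−0.50, SE 0.10), the autophagy gene Map1lc3a (−0.38, SE 0.08) and Cep170b (−0.23, SE 0.05, edgeR adjusted p = 0.0922 for each). By edgeR 0 genes passed an adjusted p of 0.05, with 2205 under an unadjusted p of 0.05 where 805 were expected by chance. Fold changes followed GC content (rho −0.382) and less so length (0.126), and with those trends removed 1409 genes were under an unadjusted p of 0.05 and the smallest edgeR adjusted p was 0.216. Limma voom called 0 and DESeq2 180 (107 higher, 73 lower, adjusted p = 2.63e-05 for Acap2 and 0.00167 for Crocc). Independent filtering left 10617 genes without a DESeq2 adjusted p, and without it the count was 73. The edgeR count was 83 without SUS 1, 184 without SUS 2, 2 without SUS 3, 3 without SUS_LE 1, 8 without SUS_LE 3 and 1 without SED 3. It was 437 with a choroid plexus score in the model. The DESeq2 count was 88, 115 and 100 without SED 1, 2 and 3, 430 and 115 without SUS 2 and 3, 43 and 41 without SUS_LE 1 and 2, and 13 with GC and length trends removed.

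**Figure D3:**
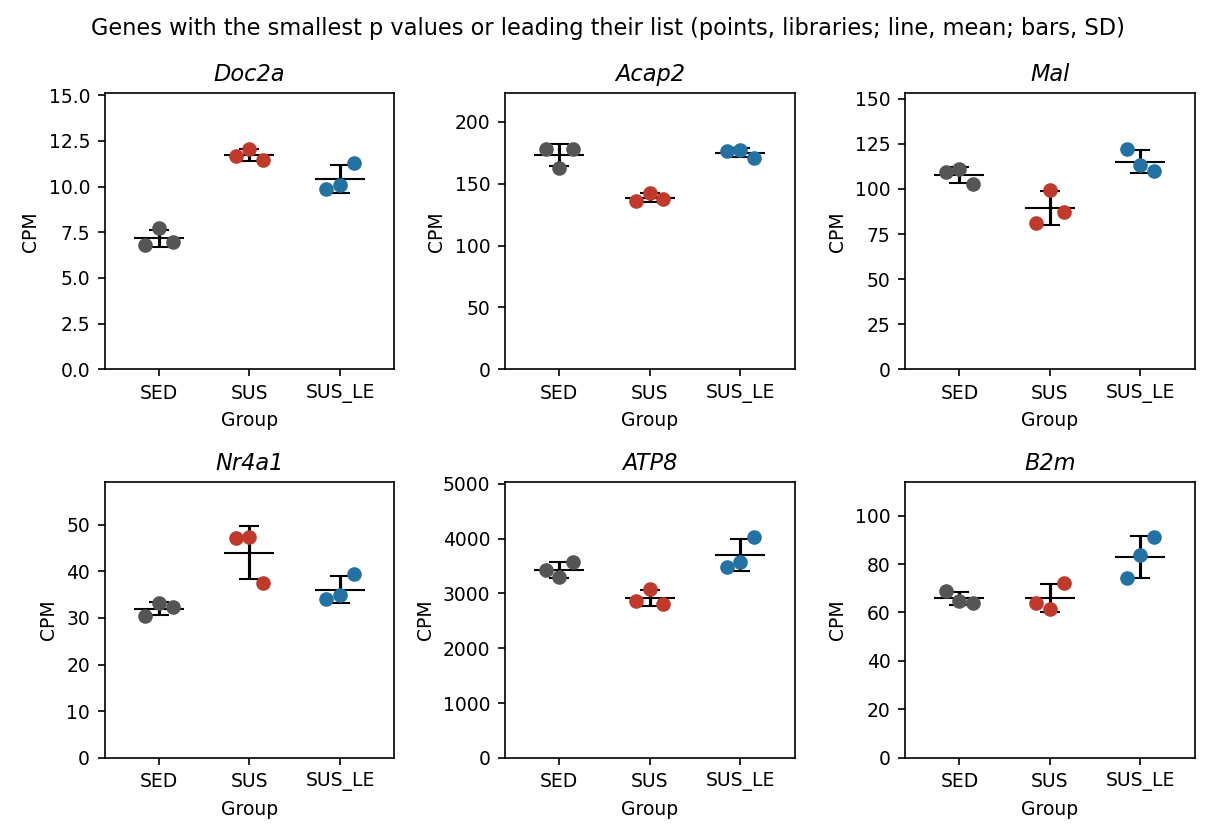
Levels of 6 genes with small p values or leading a gene list, by group. Points are mice, lines the mean and bars the SD.

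Mitochondrially encoded genes were higher in SUS_LE than in SUS in 12 of 13 members (mean 0.15, camera adjusted p = 2.02e-05, adjusted p = 0.912 with an estimated correlation). By edgeR 6 passed over the list alone and 0 over all genes, among them ATP8 (3697 ± 289.9 against 2920.1 ± 146 CPM, 0.34, SE 0.07), ND4 (0.23, SE 0.06), ATP6 (0.22, SE 0.06) and COX1 (0.21, SE 0.06). DESeq2 called 6 members of this list higher. Nuclear encoded genes of oxidative phosphorylation stood the other way, with lower values in 49 of 74 (mean −0.06, camera adjusted p = 0.00201, adjusted p = 0.912 with an estimated correlation). Uqcrq (−0.26, SE 0.06) and Atp5d (−0.24, SE 0.06) passed over the list alone, and 0 over all genes. That list no longer passed with a choroid plexus score in the model (mean −0.05, camera adjusted p = 0.0811) or with GC and length trends removed (−0.03, 0.0788). Without the 3 libraries lowest in Ttr its mean was −0.06. Ribosomal protein genes had a mean of −0.02 (37 of 78 higher, camera adjusted p = 0.418).

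Vascular, interferon and reactive astrocyte genes were higher in SUS_LE than in SUS. Vascular genes had higher values in 16 of 20 members (mean 0.26, camera adjusted p = 0.000106, adjusted p = 0.912 with an estimated correlation). Over the list alone 6 passed and 0 over all genes, such as the barrier transporters Abcb1a (40.2 ± 2.48 against 31.5 ± 1.77 CPM, 0.35, SE 0.08) and Slc2a1 (0.23, SE 0.07) and the endothelial antigens Ly6a (0.49, SE 0.15) and Ly6c1 (0.42, SE 0.13). Without SUS 2 the vascular mean was 0.14 (camera adjusted p = 0.0145). Interferon response genes had higher values in 25 of 29 members (mean 0.32, camera adjusted p = 0.000149, adjusted p = 0.912 with an estimated correlation). Gbp3 (0.87, SE 0.19), Gbp7 (0.70, SE 0.17) and B2m (0.33, SE 0.08) passed over the list alone and 0 over all genes. SUS_LE 3 held the highest interferon score of any library. Without it the mean was 0.12 (camera adjusted p = 0.0473). The mean was also 0.12 without the 3 libraries lowest in Ttr, of which SUS_LE 3 was 1. Reactive astrocyte genes had higher values in 22 of 28 members (mean 0.24, camera adjusted p = 0.000149, adjusted p = 0.846 with an estimated correlation). Over the list alone 5 passed and 0 over all genes, including H2-D1 (0.43, SE 0.11), Osmr (0.49, SE 0.13), Iigp1 (1.17, SE 0.31) and Ptgs2 (0.31, SE 0.09). Without SUS 3 the reactive astrocyte mean was 0.40 (camera adjusted p = 1.38e-06). The filter there also admits Lcn2, a list member with few counts, so that mean is not over the same members. H2-D1 and Iigp1 are also known as interferon-induced genes, and Ptgs2 is an activity-induced gene of neurons too.

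Myelin genes were higher in 18 of 24 members in SUS_LE (mean 0.10, camera adjusted p = 0.0121, adjusted p = 0.952 with an estimated correlation). By edgeR Mal, Tspan2 (0.33, SE 0.07) and Ermn (0.28, SE 0.07) passed over the list alone and 0 over all genes. DESeq2 called 3 members of this list higher. The list no longer passed without SUS 1 (mean 0.08, camera adjusted p = 0.0544), SUS 3 (0.06, 0.180) or SUS_LE 1 (0.03, 0.484). Without the 3 libraries lowest in Ttr the list's mean was 0.06. Its mean was 0.16 without SUS 2 and 0.16 without SUS_LE 3 (camera adjusted p = 0.000624 and 0.000282). Dentate granule cell genes had higher values in 12 of 15 members (mean 0.09, camera adjusted p = 0.0302, adjusted p = 0.952 with an estimated correlation, 0 over the list alone). Prox1, the granule cell transcription factor, stood at 0.34 (SE 0.11). They did not pass without SUS 2 (mean 0.03, camera adjusted p = 0.349), SUS 3 (0.10, 0.0609), SUS_LE 1 (0.01, 0.344) or SUS_LE 2 (0.07, 0.0763), with a choroid plexus score in the model (0.08, 0.158) or with GC and length trends removed (0.08, 0.0868). Without SUS_LE 3 their mean was 0.19 (camera adjusted p = 0.00215). Meningeal fibroblast genes had higher values in 14 of 15 (mean 0.36, camera adjusted p = 0.0284, adjusted p = 0.952 with an estimated correlation). That difference rested on SUS 2 (mean −0.04 without it, camera adjusted p = 0.973), and without SUS 3 it was larger (0.65, 3.13e-05). It did not pass without SUS_LE 1 (mean 0.33, camera adjusted p = 0.0947) or SUS_LE 3 (0.22, 0.241), or with a choroid plexus score in the model (0.27, 0.197). Without the 3 libraries lowest in Ttr the meningeal mean was 0.12. Erythrocyte genes had lower values in 6 of 7 (mean −0.42, camera adjusted p = 0.0125, adjusted p = 0.912 with an estimated correlation), such as the globin gene Hba-a2 (−0.73, SE 0.21). Erythrocyte genes did not pass without SUS 1 (mean −0.38, camera adjusted p = 0.0598) or SUS 3 (−0.31, 0.0653). Their mean was −0.46 without the 3 libraries lowest in Ttr. Choroid plexus genes were lower in all 20 members (mean −1.53, camera adjusted p = 0.00141, adjusted p = 0.952 with an estimated correlation). They did not pass without SUS 2 (mean −1.08, camera adjusted p = 0.0952) or SUS 3 (−0.52, 0.520), and their mean was −3.01 without SUS 1 (2.03e-17) and −2.34 without SUS_LE 2 (2.26e-06). These 3 lists had 0 members past the threshold over the list alone.

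No primary cilium list passed between SUS_LE and SUS. Intraflagellar transport and BBSome genes had a mean of −0.01 (22 of 44 higher, camera adjusted p = 0.840). Transition zone and basal body genes had a mean of −0.03 (16 of 40 higher, camera adjusted p = 0.844), and ciliary membrane and Hedgehog signalling genes 0.01 (20 of 37 higher, 0.858). Arl13b stood at 8.50 ± 0.134 CPM in SUS_LE (0.23, SE 0.15, edgeR adjusted p = 0.496), Adcy3 at 45.1 ± 1.10 (−0.04, SE 0.07, 0.826) and Ift88 at 20.1 ± 0.625 (0.02, SE 0.09, 0.950). Motile cilia genes had lower values in 31 of 41 (mean −0.18, camera adjusted p = 0.104, adjusted p = 0.952 with an estimated correlation). SUS 1 scored below every SUS_LE library (−0.79, against −0.48 to 0.03), and SUS 2 and 3 above them (0.24 and 0.43). The motile cilia list passed without SUS 1 (mean −0.56, camera adjusted p = 1.08e-10), without SUS_LE 2 (−0.31, 0.00678) and with GC and length trends removed (−0.18, 0.0295). Its mean was −0.30 without the 3 libraries lowest in Ttr. Astrocyte genes did not shift as a list (mean 0.00, median −0.01, camera adjusted p = 0.750). The mixed fry test, which counts change of either sign, gave adjusted p = 0.000983, the same as for reactive astrocyte genes. Over the list alone 6 astrocyte genes passed, and 0 over all genes. Higher values were held by Aqp4 (0.26, SE 0.06), Slc4a4 (0.24, SE 0.05), the glutamate transporter Slc1a3 (0.15, SE 0.05) and the connexin Gjb6 (0.36, SE 0.12), and lower values by the amino acid exchanger Slc7a10 (−0.48, SE 0.10) and the transcription factor Sox9 (−0.26, SE 0.07). DESeq2 called 4 astrocyte genes higher and 0 lower. Gfap (0.05, SE 0.07, edgeR adjusted p = 0.811), Bdnf (0.04, SE 0.08, 0.898), Fos (−0.02, SE 0.20, 0.980), Nr3c1 (0.14, SE 0.06, 0.333) and Fkbp5 (0.10, SE 0.14, 0.811) did not pass. Glucocorticoid responsive genes had higher values in 16 of 21 members (mean 0.13, camera adjusted p = 0.0575, adjusted p = 0.912 with an estimated correlation). Gjb6, which the astrocyte list also holds, Errfi1, Hif3a and Klf9 were higher and the clock gene Per1 lower over the list alone, and 0 passed over all genes. The list passed without SED 1, SED 2 or SED 3 (mean 0.21 each, camera adjusted p = 0.0235, 0.0231 and 0.0147), SUS 1 (0.23, 0.00419), SUS 3 (0.22, 0.0388) or SUS_LE 1 (0.23, 0.0191), where the filter also admits Lcn2, a gene with few counts, and without SUS_LE 3 (0.15, 0.0265). It also passed with GC and length trends removed (mean 0.17, camera adjusted p = 0.00395). Without the 3 libraries lowest in Ttr its mean was 0.34. The only exercised library left there is SUS_LE 2, the highest of the 9 in this score (0.16). The filter there keeps 16712 genes, against 16106 in the main fit, so the members of the list may differ too.

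**Figure D4:**
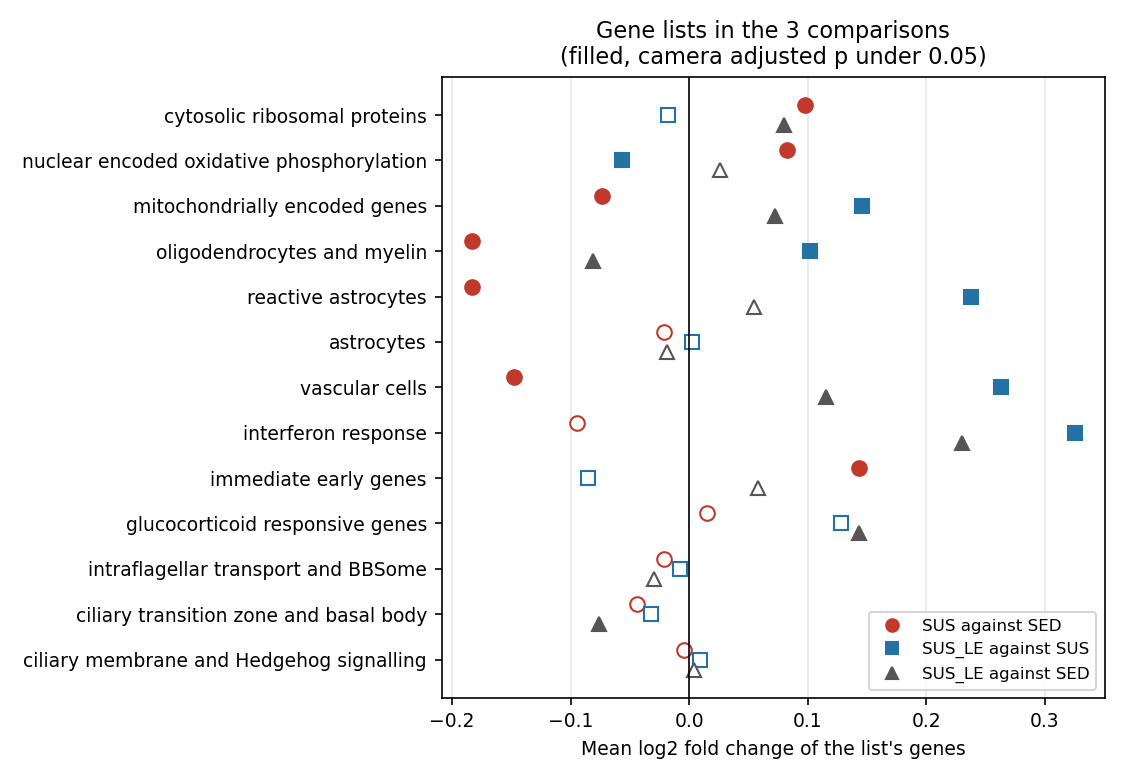
Mean log2 fold change of 13 gene lists in the 3 comparisons. Filled symbols mark a camera adjusted p under 0.05 at a preset correlation of 0.01.

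Between SUS_LE and SED, the smallest p values among genes with higher values belonged to the antigen presentation genes H2-D1 (20.0 ± 1.42 against 13.8 ± 1.42 CPM, log2 fold change 0.54, SE 0.11, edgeR adjusted p = 0.317) and B2m (0.34, SE 0.08, 0.334). Next were Doc2a (10.4 ± 0.780 against 7.16 ± 0.481 CPM, 0.54, SE 0.12, edgeR adjusted p = 0.334), Ccl27a (0.30, SE 0.07, 0.372) and Ly6a (0.61, SE 0.15, 0.382). Among genes with lower values they belonged to Lrp6, a Wnt co-receptor (66.0 ± 2.02 against 84.8 ± 2.79 CPM, −0.36, SE 0.07), Nwd1 (−0.30, SE 0.06), Serhl (−1.14, SE 0.21), 5930403L14Rik (−0.60, SE 0.11) and Myh14 (−0.39, SE 0.08, edgeR adjusted p = 0.317 for each). By edgeR 0 genes passed an adjusted p of 0.05, with 1070 under an unadjusted p of 0.05 where 805 were expected by chance. Limma voom called 0 and DESeq2 16 (2 higher, 14 lower, adjusted p = 0.0262 for Lrp6). The edgeR count was 69 without SUS 1 and 50 without SUS 3, which this comparison uses only for the spread. It was 3 without SUS_LE 1, 2 without SUS_LE 2, 1 without SED 2 or SED 3, and 239 when only SUS_LE and SED were fitted. The DESeq2 count was 3, 3 and 5 without SED 1, 2 and 3, 166, 9 and 100 without SUS 1, 2 and 3, 8, 10 and 5 without SUS_LE 1, 2 and 3, and 5 with GC and length trends removed.

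Ribosomal protein genes were again higher than in SED, in 71 of 78 members (mean 0.08, camera adjusted p = 7.04e-11, adjusted p = 0.747 with an estimated correlation, 0 over the list alone). Examples were Rps7 (163 ± 2.61 against 143 ± 3.51 CPM, 0.19, SE 0.05) and Rpl17 (0.18, SE 0.05). All 3 SED libraries had lower ribosomal scores (−0.05 to −0.07) than any SUS or SUS_LE library (−0.01 to 0.08). Glucocorticoid responsive genes had higher values in 17 of 21 members in SUS_LE (mean 0.14, camera adjusted p = 0.000572, adjusted p = 0.747 with an estimated correlation). The metallothionein Mt1 (0.20, SE 0.06) passed over the list alone and 0 over all genes, beside Klf9 (0.12, SE 0.05) and Hif3a (0.45, SE 0.20). The glucocorticoid mean ran from 0.22 to 0.27 without SED 1, 2 or 3, SUS 1, 2 or 3, or SUS_LE 1, where the filter also admits Lcn2, a gene with few counts. With a choroid plexus score in the model neither list passed (camera adjusted p = 0.0547 for both), although the glucocorticoid mean was about as large (0.15), while the ribosomal mean was 0.04. The score did not overlap between SED (1.19 to 1.75) and SUS_LE (−2.39 to 0.11), so these lost calls do not show choroid plexus content as the source.

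Choroid plexus genes were lower in SUS_LE than in SED in all 20 members (mean −2.98, camera adjusted p = 6.73e-13, adjusted p = 0.747 with an estimated correlation). Motile cilia and ependymal genes were lower in 35 of 41 (mean −0.49, camera adjusted p = 8.08e-08, adjusted p = 0.747 with an estimated correlation). Examples were Spag16 (−1.54, SE 0.49) and Tekt1 (−1.39, SE 0.45). Each had 0 members past the threshold over the list alone. The motile cilia score was lowest in SUS 1, SUS_LE 3 and SUS_LE 1 (−0.79, −0.48 and −0.22), the 3 libraries lowest in Ttr. With a choroid plexus score in the model its mean was 0.21 (camera adjusted p = 0.0590). Transition zone and basal body genes of the cilium had lower values in 30 of 40 members (mean −0.08, camera adjusted p = 0.0330, adjusted p = 0.747 with an estimated correlation, 0 over the list alone). Of the 4 named members, Tmem216 (−0.71, SE 0.25), Mks1 (−0.36, SE 0.19) and Ccp110 (62.7 ± 2.91 against 68.4 ± 2.63 CPM) had lower values. Ofd1 had higher values (14.9 ± 0.622 against 13.0 ± 0.558 CPM). That list did not pass without SED 2 (mean −0.07, camera adjusted p = 0.0828), SED 3 (−0.08, 0.0685) or SUS_LE 3 (−0.06, 0.173), or with a choroid plexus score in the model (0.00, 0.957). Without the 3 libraries lowest in Ttr its mean was −0.06. The choroid plexus score did not overlap between SUS_LE and SED, so the model with it cannot cleanly part score from group. Intraflagellar transport and BBSome genes (mean −0.03, camera adjusted p = 0.324) and ciliary membrane and Hedgehog signalling genes (mean 0.00, median −0.01, 0.808) did not pass. Nor did Arl13b (−0.05, SE 0.14, edgeR adjusted p = 0.975), Adcy3 (−0.02, SE 0.07, 0.977) or Ift88 (0.12, SE 0.09, 0.839).

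Mitochondrially encoded genes had higher values in 12 of 13 members in SUS_LE than in SED (mean 0.07, camera adjusted p = 0.00737), and interferon response genes in 22 of 29 (mean 0.23, 0.01). So did vascular genes in 18 of 20 (mean 0.12, camera adjusted p = 0.0330) and circadian clock genes in 14 of 17 (mean 0.09, 0.0330). Each of the 4 lists had adjusted p = 0.747 with an estimated correlation. Myelin genes had lower values in 18 of 24 (mean −0.08, camera adjusted p = 0.0330, adjusted p = 0.773 with an estimated correlation). Over the list alone B2m, Ly6a, Abcb1a (0.26, SE 0.08) and the myelin list member Trf (−0.22, SE 0.06) passed, and 0 over all genes. Without SUS_LE 3 the interferon mean was 0.03 (camera adjusted p = 0.765), and without SUS_LE 2 it was 0.41 (8.28e-06). The mitochondrial (mean 0.03, camera adjusted p = 0.232), vascular (0.08, 0.232), myelin (−0.02, 0.765) and circadian (0.08, 0.141) lists did not pass without SUS_LE 3 either. The circadian list also did not pass without SED 1 (mean 0.06, camera adjusted p = 0.330), SED 3 (0.08, 0.149) or SUS_LE 1 (0.07, 0.129), and its mean was 0.14 without SED 2 (0.00183). Nor did the vascular list pass without SED 2 (mean 0.11, camera adjusted p = 0.156), or the myelin list without SED 2 (−0.05, 0.244), SED 3 (−0.09, 0.0503), SUS 1 (−0.08, 0.0511) or SUS_LE 2 (−0.07, 0.135). The myelin mean was −0.15 without SUS_LE 1 (camera adjusted p = 1.88e-05). Without the 3 libraries lowest in Ttr, SUS_LE 2 alone gave the mitochondrial (0.02), interferon (−0.00467), vascular (0.04), circadian (0.03) and myelin (−0.11) means. The choroid plexus score did not overlap between SED and SUS_LE, so lost calls need not come from choroid plexus content. With that score in the model 0 lists passed. The circadian and myelin means then stayed about as large (0.09 and −0.07, camera adjusted p = 0.252 and 0.292), and the interferon (0.17, 0.145), vascular (0.08, 0.252) and mitochondrial (0.03, 0.252) means were smaller. Astrocyte genes had a mean of −0.02 and a median of 0.03 (camera adjusted p = 0.625). Gfap (0.13, SE 0.07, edgeR adjusted p = 0.774), Aqp4 (0.04, SE 0.06, 0.959), Bdnf (0.12, SE 0.08, 0.831), Fos (−0.31, SE 0.20, 0.827), Nr3c1 (0.00, SE 0.06, 0.999) and Fkbp5 (0.10, SE 0.14, 0.944) did not pass.

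Several genes with lower values in SUS than in SED stood near the SED level in SUS_LE. Acap2 was at 173, 139 and 175 CPM in SED, SUS and SUS_LE, and Taok1 at 250.2, 196 and 241. The tight junction gene Tjp1 (130.1, 105 and 130 CPM) and Xkr4 (120, 93.5 and 120 CPM), chosen after their values were seen, had the same course, while Doc2a, at 7.16, 11.7 and 10.4 CPM, did not. DESeq2 called 19 genes higher in SUS than in SED and lower in SUS_LE than in SUS, and 34 the other way. Both comparisons use the same SUS libraries, so chance alone makes their fold changes oppose each other. In simulated data without group differences, in which genes vary independently, as many genes with the smallest p overlapped in at most 13 and 24. With GC and length trends removed the calls in the 2 comparisons came to 20 and 13, from 163 and 180. Over all genes the covariance of the fold changes was −0.0242, against −0.0290 in the simulated data (excess 0.00482, SD of simulations 0.00180), although signs were opposite in 72.1% of genes against 66.7% simulated. With GC and length trends removed signs were opposite in 67.8% of genes, against 66.7% simulated. The excess covariance was −0.0105, 0.00857 and −0.00515 without SUS 1, 2 and 3, 0.0104 and 0.000359 without SUS_LE 2 and 3, and 0.00804 without SED 3. Among 13631 genes apart from the choroid plexus score within groups it was −0.00858 (SD of simulations 0.00212). For SUS and SUS_LE against the shared SED libraries it was 0.0124 over all genes, 0.00193 without SED 1, −0.00312 without SUS 1, 0.0338 without SUS 3 and 0.0206 without SUS_LE 2, and −0.00198 among the 13631 genes. That last value had no stable sign (−0.00675 and 0.00104 without SED 1 and 2, 0.00867 without SUS 3 and 0.000660 without SUS_LE 2). In the test for any difference among the 3 groups, edgeR called 0 genes (smallest adjusted p = 0.0621, 2171 under an unadjusted p of 0.05). It called 68 without SUS 1, 13 without SUS 2, 86 without SUS 3, 2 without SED 2 or SUS_LE 1, and 1 without SED 3 or SUS_LE 2. It called 198 with a choroid plexus score in the model.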

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

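The choroid plexus covariate, leaving out the 3 libraries lowest in Ttr, the GC and length offsets, TMM factors in DESeq2 and DESeq2 without each library were chosen after the results were seen. Counts of changed genes are given for SUS against SED, SUS_LE against SUS and SUS_LE against SED in that order, then for any group; where a cause is not stated, the cause was not tested. By edgeR they were 0, 0, 0 and 0, and they stayed at 0 with relative log expression or upper-quartile factors, with a filter of at least 1 CPM in 3 libraries and with GC and length offsets; limma voom gave 0, 0 and 0. DESeq2 gave 163, 180 and 16, with TMM factors 157, 191 and 10, and with GC and length offsets 20, 13 and 5, of which 14, 13 and 5 were among the first. Without independent filtering, also chosen after the results were seen, DESeq2 gave 53, 73 and 16, and 2, 13 and 5 with the offsets. With no filter beyond 1 count they were 297, 430, 218 and 695 of 26992 genes, where the prior degrees of freedom of the dispersion became infinite (median 12.8 as designed). With only the 2 groups compared they were 0, 1 and 239, with a non-robust dispersion 0, 1 and 1, with the choroid plexus covariate 0, 437, 2 and 198, and without the 3 libraries lowest in Ttr, which leaves SUS_LE with 1 library assumed to vary like the others, 14, 20, 16 and 30. Leaving out 1 library gave 0 to 74, 0 to 184, 0 to 69 and 0 to 86 by edgeR, and 7 to 277, 41 to 430 and 3 to 166 by DESeq2.

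Replicate number as a block gave 1, 1, 0 and 1 changed genes. The labels do not pair the mice, and deviations of libraries with the same number correlated at −0.12 to 0.18, with 2 of 9 pairs over 0.1 and 5 of 9 libraries closest to their own number, so the numbers were not used as pairs.

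Lists past the threshold numbered 9, 10 and 10. They were 0, 0 and 0 with an estimated correlation, 0, 0 and 0 by fry for 1 direction (smallest adjusted p = 0.0803, 0.162 and 0.257), 8, 6 and 0 with the choroid plexus covariate, 12, 8 and 4 without the 3 libraries lowest in Ttr, and 4 to 12, 8 to 12 and 6 to 11 without 1 library, while upper-quartile factors left every one of 105 list results on its side and GC and length offsets and the block kept the counts within 1.5 times. Mean fold changes of lists past the threshold that turned were motile cilia in SUS against SED (0.0343 with the choroid plexus covariate, 0.0670 without the 3 libraries lowest in Ttr, −0.542 to 0.0699 without 1 library, the last without SUS 1), choroid plexus in SUS against SED (0.0201 without the 3 libraries, −2.47 to 0.0231 without 1 library, the last without SUS 1), meningeal fibroblasts in SUS_LE against SUS (−0.0443 without SUS 2 to 0.648 without SUS 3), and, with the choroid plexus covariate, the transition zone list (0.00250) and motile cilia (0.21) in SUS_LE against SED, and interferon response in SUS_LE against SED without the 3 libraries (−0.00467). Of 172 gene results 78 kept direction and side of the threshold in all settings, 17 changed sign in some and 77 gained a call in some. Of 105 list results 18 kept both, 48 changed sign, 21 gained and 29 lost a call in some setting.

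The excess covariance of the fold changes, 0.00482 (0.0124 against SED), was 0.00395 (0.0121) with the stricter filter, 0.00775 (0.0123) with GC trends removed −0.00858 (−0.00198) among genes apart from the choroid plexus score within groups, and −0.00630 (−0.00644) when these were chosen over all 9 libraries. The last choice also removes genes by their group means, since the score falls from SED to SUS_LE, so its values decide nothing. Without 1 library it ran from −0.0105 to 0.0104 (−0.00312 to 0.0338), with the lowest value without SUS 1 in both. Alternatives for normalized values do not apply, since the files hold counts, and the choroid plexus list has no value under its own score as a covariate. At the present depth the smallest simulated change was recovered in 28%, 30% and 24% of genes, so smaller differences would mostly be missed.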

Other observations

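Tests of choroid plexus marker correlation, of the SUS_LE and SED choroid plexus scores, and of opposing fold changes among genes apart from that score were chosen after the result was seen. Genes of the glutamatergic synapse had a mean log2 fold change of 0.05 in SUS against SED (28 of 45 higher, camera adjusted p = 0.111), with higher values over the list alone of Nrxn2, a presynaptic adhesion gene (0.25, SE 0.06), and the vesicle fusion genes Stx1a (0.28, SE 0.06) and Vamp2 (0.25, SE 0.06), and 0 over all genes. In SUS_LE against SUS the mean was −0.03 (26 of 45 lower, camera adjusted p = 0.445), and members with lower values over the list alone included Nrxn2 (−0.26, SE 0.06), Stx1a (−0.21, SE 0.06) and the postsynaptic gene Shank1 (−0.29, SE 0.08). Against SED, SUS_LE had a mean of 0.02 (camera adjusted p = 0.431). The list passed without SUS 3 in the first 2 comparisons (camera adjusted p = 0.00158 and 0.0112), and with GC and length offsets in SUS against SED (mean 0.09, 0.000619) and SUS_LE against SED (mean 0.06, 0.0229). SUS 3 scored −0.053, below SUS 1 and 2 (0.08 and 0.05) and every SED library (−0.048 to −0.003). In the main fit adjusted p with an estimated correlation was 0.726 and 0.952 in the first 2 comparisons. Per1, a clock gene that glucocorticoids induce, stood at 55.4 ± 4.59 CPM in SED, 70.2 ± 5.88 in SUS and 60.2 ± 1.19 in SUS_LE, and Clock at 132 ± 4.90, 113 ± 11.3 and 123 ± 3.15. Microglial genes did not shift in 1 direction in SUS against SED, SUS_LE against SUS or SUS_LE against SED (camera adjusted p = 0.623, 0.410 and 0.535), nor did genes of GABAergic interneurons (0.151, 0.858 and 0.203), CA1 pyramidal cells (0.310, 0.969 and 0.324) or adult neurogenesis (0.557, 0.301 and 0.535), of which adult neurogenesis passed in SUS_LE against SUS without SUS 2 (mean −0.21, camera adjusted p = 0.0219). In SUS against SED the mixed fry test, which counts change of either sign, gave adjusted p = 0.0382 for microglial and 0.0177 for GABAergic genes. Under an unadjusted p of 0.05 there were 0 higher and 3 lower microglial members, and 4 higher and 1 lower GABAergic members. Over the list alone 0 members of either list passed.

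Chtf8, chosen after its values were seen, was at 0 CPM in all 3 SUS_LE libraries, 35.4 ± 0.454 in SUS and 25.3 ± 16.4 in SED (DESeq2 adjusted p = 2.41e-11 for SUS_LE against SED, edgeR adjusted p = 0.550). Its values spread widely within SED. The source of the 0 values was not tested, so they are not read as an effect of exercise. The histone gene H2ac18, chosen in the same way, stood at 1.08 ± 0.679 CPM in SUS_LE, 4.23 ± 1.34 in SUS and 4.61 ± 1.19 in SED (DESeq2 adjusted p = 0.000483 for SUS_LE against SED, edgeR adjusted p = 0.334). Values of the 3 libraries did not overlap in 18.3%, 17.0% and 16.2% of genes in the 3 comparisons, where chance gives 10.0%.

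Choroid plexus markers differed within SUS and within SUS_LE by far more than other lists. The 20 markers moved together over the 9 libraries (median pairwise r 0.983), which is what unequal amounts of choroid plexus in the dissected tissue would give, and the lowest library, SUS 1, kept 27.4 CPM of Ttr. A lowering shared by all mice of a group would not give the spread within SUS (Ttr 27.4 to 6085 CPM) or within SUS_LE (59.6 to 1509). A lowering that differs in degree between mice could give both that spread and such an r, so r favours neither. For the difference between groups a lowering by stress and exercise stays open too. The score differed between SUS_LE and SED by −2.98 with an exact permutation p = 0.1, the smallest that 3 against 3 can give (p = 0.6 for SUS against SED and 0.4 for SUS_LE against SUS). Unequal amounts and a lowering may both add to the group difference, and the 2 cannot be told apart with 3 mice per group.

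Among genes whose spread within groups went apart from the choroid plexus score, the covariance of fold changes of SUS against SED and of SUS_LE against SUS was more negative than in simulated data with shared SUS libraries, in which genes vary independently (excess covariance −0.00858, −0.0128 to −0.00628 without 1 library), while over all genes it was not (0.00482). Whether SUS 1 is the source stays open, since the measures part without it: 149% of the excess covariance remained (−0.0128, with the simulated covariance going from −0.0265 to −0.0375), while r went from −0.548 against −0.502 simulated to −0.596 against −0.6, and opposite signs from 73.0% of genes against 66.7% simulated to 72.5% against 70.5%. Without SUS 3 r did not exceed the simulated value either (−0.592 against −0.602). GC and length trends may hold part of it, by a share that differs between measures. With them removed 66.0% of the excess covariance remained (−0.00566, against an SD of 0.00227 over libraries left out). Of the excess in r 56.6% remained, and of that in opposite signs 30.7% (68.6% of genes against 66.7% simulated). Sets with 1 library left out share most libraries, so that SD understates the spread between mice and decides nothing here. The DESeq2 counts of 163 and 180 came to 20 and 13. A return toward the SED level with exercise stays open and was not tested, since a second group of SUS mice is not used here.

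Ribosomal protein genes stood above SED in both stressed groups (mean log2 fold change 0.0886 over the 2 comparisons, 0.0796 to 0.0961 without 1 library). Short transcripts and GC content could produce such a shift, but 74.8% of it remained with GC and length offsets (0.0663, against an SD of 0.00477 over libraries left out), which argues against them as the whole source. That SD understates the spread between mice, since sets with 1 library left out share most libraries. Reads shared with ribosomal pseudogenes and an effect of stress itself were not tested and stay open, and with an estimated correlation the list did not pass in either comparison. With a choroid plexus score in the model the mean was 0.0786 in SUS against SED and came to 0.0410 in SUS_LE against SED, where the list no longer passed (camera adjusted p = 0.0547), so a part tied to choroid plexus content stays open there.

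The 10 splits of 6 libraries into 3 and 3 cannot give a share under 0.1. By edgeR all 10 splits gave at least the real count of 0 in each comparison, as any split must, so this tally decides nothing; the highest other counts were 1 (SUS and SED), 14 (SUS_LE and SUS) and 1 (SUS_LE and SED). By DESeq2 1 of 10 splits, the real one, reached the real count in each: 163 against 11 at most in other splits, 180 against 175, and 16 against 7. The split with 175 set SUS 1, SUS_LE 1 and SUS_LE 3, the libraries lowest in Ttr, against the other 3, and points to a structure of the samples apart from the groups. For lists past the threshold 3 of 10 splits reached the real count in SUS against SED (9, highest other 10), 5 of 10 in SUS_LE against SUS (10, highest other 13) and 1 of 10 in SUS_LE against SED (10, highest other 9). For any difference among the groups, 100 of 100 splits of the 9 libraries, drawn at random with the real one included, gave at least the real count of 0, which any split must and which decides nothing, and the highest gave 128, which again points to structure apart from the groups.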
